A study of Mus musculus with 4 samples.

How the data were processed

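RNA from sorted mouse airway epithelial cells, 2 libraries from mice given HDM and 2 from mice given PBS, was made into libraries with a SMARTer kit, per the labels' protocols. Reads were trimmed with cutadapt and the genome build was mm10, per the submitters' processing notes, while the aligner, the read counter, the annotation and the strand setting are not given in the sources used here. The deposited table gives raw read counts per gene and library, per the file headers, which mark these columns as Input. It also holds 4 further columns of per-sample normalized values, which were not used here. Library groups and replicate numbers were taken from the labels.

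Counts were analysed in R 4.3.3. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 12852 of 16501 genes and at least 99.9% of the reads of each library. Libraries were scaled by the TMM method (factors 0.969 and 0.990 for PBS replicates 1 and 2, and 1.04 and 1.00 for HDM), and CPM are counts per 1e6 reads of the scaled library. HDM was compared with PBS by edgeR's quasi-likelihood test (edgeR 4.0.16, glmQLFit and glmQLFTest, treatment as the only term, two-sided), with Benjamini-Hochberg adjustment at 0.05. Fold changes are HDM over PBS. The standard error of a log2 fold change was taken from the F statistic, and its 95% interval from the test's degrees of freedom. Intervals and the floor of 3 reads that a count of 0 allows cover no more than the spread and counting error of these libraries, since PCR copies are not independent molecules.

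A set of 30 gene lists (463 distinct genes, of which 394 were matched to the table, 9 of them by another symbol, and 319 were tested) was fixed before the data were examined. Lists with at least 3 tested genes were tested with limma 3.58.1's camera (preset correlation 0.01, two-sided, Benjamini-Hochberg over 26 lists), with an estimated correlation and with fry, which asks whether a list's own genes move one way on balance. Named genes were chosen by a rule set before the data were examined. It takes the study genes and sort markers. It takes genes past the threshold or, since none passed, the 10 of smallest p in each direction with both HDM libraries on the same side of both PBS libraries and a mean of at least 5 CPM in the higher group, without unnamed gene models. From each list it takes up to 4 genes of smallest p. It gave 123 tested genes, and the report prints part of them, picked after their values were seen. Gene positions and GC content are from GENCODE release 21 for mouse (mm10), and 98.2% of tested genes had a GC value.

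The libraries of a group were checked for being 1 library deposited repeatedly: their counts differed far beyond sampling noise (chi-square per degree of freedom 64.2 for PBS and 150 for HDM). The test was run on data simulated from these libraries' means, sizes and dispersion (20 simulations, 12852 genes). It called 8.42% of genes changed 2-fold (165 calls), 67.8% of those changed 4-fold (1318) and 0.067% of unchanged genes (166). Camera called a list shifted by a log2 of 1 in 20 of 20 simulations. That shift is larger than the median of any called list. Genes were drawn independently, with the same dispersion in each library. The simulations therefore do not cover correlation between genes or a library that stands apart. The biological coefficient of variation was 0.316.

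Alternatives set before the data were examined were a replicate block, each library left out, no filter and a filter of 50 reads in 2 libraries, median-of-ratios factors, quantile normalization with limma, DESeq2 1.42.0, limma-trend, other thresholds, fry, an estimated correlation and lists without shared genes. The removal of each library's GC trend (natural spline, 5 degrees of freedom), alone or with the replicate block, was added after the data were seen, as were tests of GO terms given in the table with 15 to 500 tested genes. Where 1 library of a group remained, it was assumed to vary like the other group. Genes with near-identical copies or antisense partners are reported with that uncertainty.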

Results

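Transcript levels were measured by RNA sequencing in airway epithelial cells that had been sorted by flow cytometry from the lungs of wild-type mice. The sort used antibodies against CD326, the epithelial surface protein encoded by Epcam, and against CD45, the pan-leukocyte surface protein encoded by Ptprc. The mice had received HDM (house dust mite, a common source of inhaled allergens) or PBS (phosphate-buffered saline, the vehicle), and each treatment is represented by 2 libraries. The table holds read counts for 16501 genes, with totals of 19582866 reads in PBS replicate 1, 30189421 in PBS replicate 2, 14286679 in HDM replicate 1 and 22070104 in HDM replicate 2. No label says whether the libraries of a treatment came from separate animals, so the p-values given here measure the spread between these samples, which may be technical.

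The study asks how YTHDF1, a cytoplasmic reader of N6-methyladenosine in mRNA, and CLOCK, a transcription factor of the circadian clock, take part in allergic airway inflammation. Clock (ENSMUSG00000029238, chromosome 5, 76209868 to 76304792, minus strand, mm10) stood at 82.2 ± 10.5 CPM (counts per 1e6 reads of the scaled library) in PBS and 126 ± 0.42 CPM in HDM (SD, n = 2 each), and both HDM libraries lay above both PBS libraries. The fold difference was 1.54, with a 95% confidence interval of 1.07 to 2.21, and the log2 fold change was 0.62 with a standard error of 0.23. It did not pass across genes (edgeR quasi-likelihood test, unadjusted p = 0.0267, Benjamini-Hochberg adjusted p = 0.883). Ythdf1 (ENSMUSG00000038848, chromosome 2, 180904377 to 180920949, minus strand) stood at 60.2 ± 6.94 CPM in PBS and 51.7 ± 13 CPM in HDM, with a log2 fold change of -0.22 and an interval from -0.83 to 0.39 (edgeR adjusted p = 0.926). Epcam (ENSMUSG00000045394, chromosome 17, 87635979 to 87651129, plus strand), the sorted epithelial marker, stood at 256 ± 15.8 CPM in PBS and 247 ± 42.2 CPM in HDM (edgeR adjusted p = 0.984). Ptprc was too low to be tested, with 8 reads in PBS replicate 1 and 0 reads in each of the other 3 libraries, where 3 reads would correspond to between 0.10 and 0.20 CPM. Clock transcripts are AT-rich (40.9% GC), and in a fit that removed each library's dependence on GC content, chosen after the data were seen, the log2 fold change of Clock was 0.33 (edgeR unadjusted p = 0.160).

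**Figure D1:**
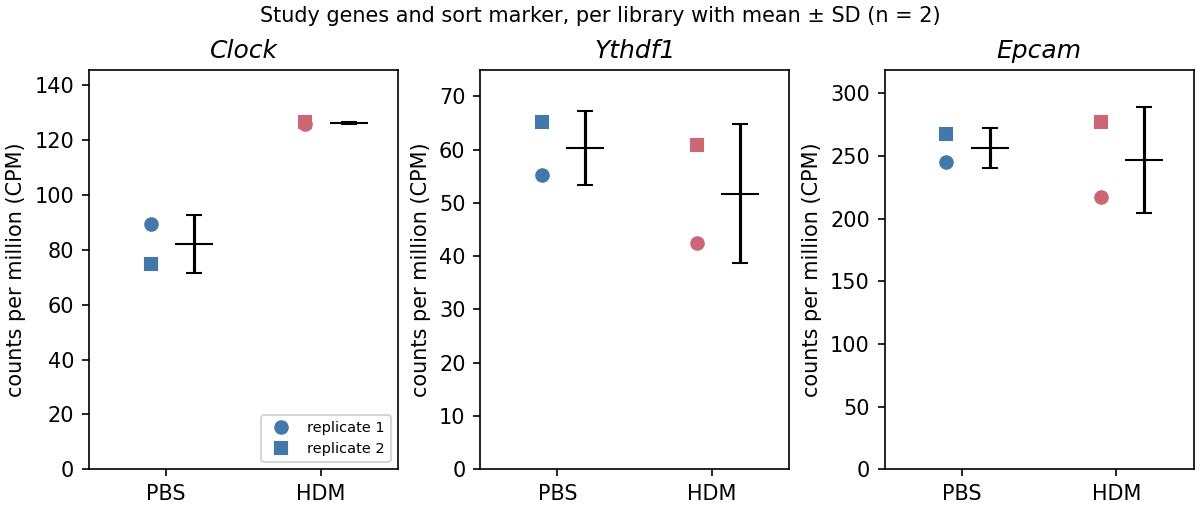
CPM (linear axis from 0) of Clock, Ythdf1 and Epcam in each library, with circles for replicate 1, squares for replicate 2 and black bars for the group mean ± SD (n = 2). Clock sits at 89.6 and 74.8 CPM in the PBS libraries and at 126 and 127 CPM in the HDM libraries, while the Ythdf1 and Epcam values of the groups overlap.

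The broad comparison asked which genes differ between HDM and PBS, and the 10 genes of smallest p on the higher side come first. Npm1, an abundant nucleolar protein gene, stood at 202 ± 6.59 CPM in PBS and 431 ± 69.8 CPM in HDM (log2 fold change 1.09), and Ddx50, a nucleolar RNA helicase gene, at 38.3 ± 2.23 and 71.2 ± 1.69 CPM (log2 fold change 0.89). Upf2, a factor of nonsense-mediated mRNA decay, stood at 18.8 ± 3.84 CPM in PBS and 40.3 ± 5.14 CPM in HDM, and Atr, a DNA damage checkpoint kinase gene, at 22.0 ± 5.18 and 46.4 ± 3.86 CPM. Dek, a chromatin protein gene, Dnajc2, a ribosome-associated chaperone gene, Gcfc2 and Zfp52 had log2 fold changes of 1.07, 1.03, 1.36 and 1.12. Nod2, an intracellular sensor of bacterial peptidoglycan, stood at 0.785 ± 0.215 CPM in PBS against 10.8 CPM in HDM replicate 1 and 3.08 CPM in HDM replicate 2. Samd12 stood at 7.04 ± 0.266 CPM in PBS against 33.8 CPM in HDM replicate 1 and 15.3 CPM in HDM replicate 2. None of these genes passed the test (edgeR, adjusted p = 0.883 for each). Apart from Nod2 (54.4% GC), they are AT-rich, with 39.2% (Dek) to 45.5% GC (Gcfc2). In the fit that removed each library's dependence on GC content, these AT-rich genes kept their direction with smaller log2 fold changes. Dek went from 1.07 to 0.74, Npm1 from 1.09 to 0.85 and Gcfc2 from 1.36 to 1.22. That of Nod2 did not shrink (3.12 and 3.18). The reads of Npm1 can be shared with its processed pseudogenes, which makes its level uncertain.

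The 10 genes of smallest p on the lower side follow. Scnn1g, a subunit of the epithelial sodium channel, stood at 180 ± 30.9 CPM in PBS and 90.2 ± 13.6 CPM in HDM, and Phgr1, a gene of mucosal epithelium, at 41.8 ± 8.37 and 18.3 ± 2.12 CPM (log2 fold change -1.19). Timp1, an inhibitor of matrix metalloproteinases, stood at 114 ± 20.4 CPM in PBS and 59.8 ± 13.2 CPM in HDM. Cyp4b1, a cytochrome P450 gene of club cells, stood at 57.1 ± 20.2 CPM in PBS and 28.4 ± 2.18 CPM in HDM, and Mgst3, a microsomal glutathione transferase gene, at 36.6 ± 4.06 and 20.5 ± 0.99 CPM. The mitochondrially encoded mt-Co3 stood at 179 ± 5.19 CPM in PBS and 101 ± 18.4 CPM in HDM. Slc10a3, Pmp22, Tuba1b and Hist2h2aa2 had log2 fold changes of -1.04, -0.81, -1.17 and -1.42, and the last pair have close copies that could take or give reads. None of the 10 genes passed (edgeR, adjusted p = 0.883 for each).

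Over all 12852 genes tested, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes, with 577 genes at an unadjusted p under 0.05 (404 higher and 173 lower in HDM) where chance would give 643. DESeq2 called 1 gene, Gm20721, which stood at 1.76 ± 0.497 CPM in PBS and 14.4 ± 5.87 CPM in HDM and is named here after its values were seen. Both HDM libraries lay above both PBS libraries for 2446 genes (19.0%) and below them for 2302 (17.9%), and chance gives 16.7% each way. The count depends on the libraries and the filter: without a filter 85 genes were called. With HDM replicate 1 as the lone HDM sample, 994 genes were called, and with HDM replicate 2 as the lone one, 1 gene was called. With genes simulated independently at this comparison's spread, the test called 8.42% of genes changed 2-fold and 67.8% of genes changed 4-fold.

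Among the fixed gene lists, the clearest shift was in cholesterol and lipid synthesis, where all 21 genes tested had a log2 fold change below 0 and 10 lay lower in both HDM libraries than in both PBS libraries. Elovl1, an elongase of long-chain fatty acids, stood at 107 ± 7.29 CPM in PBS and 65.6 ± 6.93 CPM in HDM. Dhcr7, a reductase of cholesterol synthesis, stood at 55.8 ± 1.19 CPM in PBS and 33.8 ± 4.96 CPM in HDM. Fdps, which makes farnesyl diphosphate, stood at 241 ± 54.3 and 153 ± 31.0 CPM. The list was lower in HDM relative to the other genes (camera, adjusted p = 5.96e-05, and adjusted p = 0.759 with an estimated correlation), with a median log2 fold change of -0.46. The median was -0.85 in HDM replicate 1 and -0.15 in HDM replicate 2, and without HDM replicate 1 the camera adjusted p was 0.327.

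Lists of club cells and alveolar epithelium were also lower in HDM. In the club cell list 10 of 12 genes were below 0 (camera, adjusted p = 0.0422, and 0.759 with an estimated correlation). Cyp2f2, a cytochrome P450 gene of club cells, stood at 291 ± 117 CPM in PBS and 124 ± 64.8 CPM in HDM. Cbr2, a carbonyl reductase gene, stood at 206 ± 13.7 and 143 ± 19.3 CPM, and Scgb3a1, a secretoglobin gene, at 8.29 ± 2.10 and 4.03 ± 1.22 CPM. The summed level of the club list was 6332 CPM in PBS replicate 1 and 6247 CPM in HDM replicate 1. In PBS replicate 2 and HDM replicate 2 it was 4040 and 3696 CPM. The sum thus differed more by replicate number than by treatment. In the alveolar type 1 list 11 of 12 genes were below 0 (camera, adjusted p = 0.0320, and 0.759 with an estimated correlation), among them Gprc5a at 1521 ± 248 CPM in PBS and 979 ± 123 CPM in HDM and Emp2 at 3331 ± 157 and 2130 ± 555 CPM. In the transitional alveolar list, a keratin-high state of injured alveolar epithelium, 11 of 14 genes were below 0 (camera, adjusted p = 0.0320, and 0.759 with an estimated correlation). There Krt19, an epithelial keratin gene, stood at 2670 ± 10 CPM in PBS and 1963 ± 27.4 CPM in HDM, and Cldn4, a tight junction gene, at 1372 ± 36.8 and 950 ± 31.3 CPM. The median of this list was -0.31 in HDM replicate 1 and -0.32 in HDM replicate 2, and that of the club list -0.46 and -0.48. The transitional alveolar and club lists lost their calls after GC correction (camera, adjusted p = 0.775 and 0.137), with medians of log2 fold change going from -0.30 to -0.20 and from -0.31 to -0.35, so that of the club list did not shrink. Without HDM replicate 1 the transitional alveolar list stayed called and the other pair did not, and without HDM replicate 2 only the alveolar type 1 list stayed called. Without PBS replicate 1 none of the 3 lists was called (alveolar type 1 0.228, transitional alveolar 0.130, club 0.146, camera adjusted p). Without PBS replicate 2 the transitional alveolar list was not (0.0851), and the alveolar type 2, macrophage and monocyte, and mitochondrially encoded lists were (0.0131 each, lower). With quantile normalization none of the 3 lists was called. Over the 4 libraries Scgb1a1 of club cells had a mean of 18 CPM, Sftpb of alveolar type 2 cells 0.234 CPM and Ager of alveolar type 1 cells 0.0659 CPM. These lists rest on part of their members and do not establish which cell types the libraries hold.

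Genes of the mesenchymal list were lower in HDM by the same test (12 of 15 below 0, camera adjusted p = 0.0302, and 0.759 with an estimated correlation). The summed level of the list overlapped between groups. It was 6586 and 7904 CPM in PBS replicates 1 and 2, and 6928 and 6526 CPM in HDM replicates 1 and 2. Msln, its most abundant gene, stood at 3678 and 3626 CPM in PBS and at 5203 and 2734 CPM in HDM. The fibrillar collagen genes Col1a1, Col1a2 and Col3a1 stood at 579 ± 139, 396 ± 9.37 and 188 ± 18 CPM in PBS and at 314 ± 123, 226 ± 90.7 and 111 ± 25.7 CPM in HDM. The list's median was -1.10 in HDM replicate 1 and 0.16 in HDM replicate 2, and its call ended without HDM replicate 1, without PBS replicate 2, after GC correction and with quantile normalization (camera, adjusted p = 0.657, 0.115, 0.138 and 0.0561). After GC correction its median log2 fold change was -0.34, against -0.31 before, so the shift did not shrink with that call.

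The list of NF-kB targets, chemokines and acute phase genes was the only called list that lay higher (11 of 13 above 0, median log2 fold change 0.75, camera adjusted p = 0.0397, and 0.759 with an estimated correlation). Its height was in HDM replicate 1. Nfkbia, the NF-kB inhibitor induced by NF-kB itself, stood at 274 CPM in HDM replicate 1 and between 32.7 and 42.4 CPM in the other 3 libraries. Cxcl1, a neutrophil chemokine gene, stood at 18.4 CPM there and at 1.22 CPM in HDM replicate 2, against 0.675 ± 0.134 CPM in PBS, and Tnfaip3 at 337 CPM against 97.2 in HDM replicate 2. The dissociation stress list showed the same contrast. The inducible heat-shock genes Hspa1b and Hspa1a, near-identical copies whose reads cannot be parted with certainty, stood at 1579 and 471 CPM in HDM replicate 1 and at no more than 41.9 and 14.1 CPM elsewhere. Dnajb1, their cochaperone gene, stood at 1211 CPM there and between 90.8 and 102 CPM elsewhere. That list was not called over all 4 libraries (camera, adjusted p = 0.235) and was called with HDM replicate 1 as the lone HDM library (adjusted p = 0.000365). Without HDM replicate 1 the NF-kB list had a camera adjusted p of 0.657, and without PBS replicate 1 of 0.0986. With the strict filter it was 0.0555 and with quantile normalization 0.0561.

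**Figure D2:**
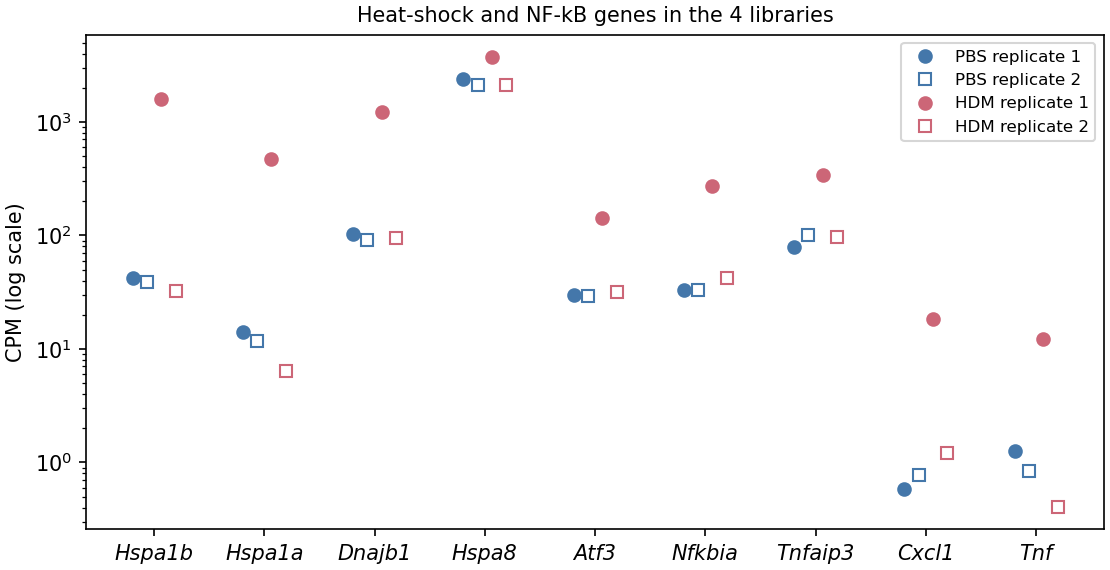
CPM (log axis) of heat-shock, stress and NF-kB genes in each library, with filled circles for replicate 1 and open squares for replicate 2, blue for PBS and red for HDM. HDM replicate 1 is the highest of the 4 libraries for all 9 genes, with Hspa1b at 1579 CPM against 32.6 CPM in HDM replicate 2.

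Of the 20 circadian clock genes tested, 12 lay above 0 and 8 below (camera, adjusted p = 0.356). Nr1d2, a repressor in the secondary loop of the clock, stood at 29.9 ± 1.04 CPM in PBS against 86.0 CPM in HDM replicate 1 and 38.3 CPM in HDM replicate 2, and Rora, its activating counterpart, at 16.6 ± 5.01 CPM against 51.5 and 22.5 CPM. Tef, a clock-controlled transcription factor gene, stood at 162 ± 30.6 CPM in PBS and 90.9 ± 31.0 CPM in HDM. The list was called only with HDM replicate 1 as the lone HDM library (camera, adjusted p = 0.0476). Of the 20 genes of the m6A machinery, 11 lay above 0 and 9 below, with a median of 0.14 (camera, adjusted p = 0.375). Rbm15, an adaptor of the methyltransferase, stood at 25.7 ± 0.378 CPM in PBS and 40.5 ± 16.5 CPM in HDM, and Mettl14, a methyltransferase subunit gene, at 12.7 ± 0.70 and 17.5 ± 3.76 CPM.

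Lists tied to allergic inflammation gave no call over all 4 libraries in the main setting. Tested were 9 of 20 genes of the type 2 cytokine response list, 7 of 20 of goblet and mucus and 7 of 13 of epithelial alarmins. The remaining genes were too low to be tested or unmatched. These lists had camera adjusted p = 0.662, 0.235 and 0.662. In that order, 5, 2 and 5 genes had a log2 fold change above 0, and 4, 5 and 2 below. Without PBS replicate 1 the goblet and mucus list was called lower (adjusted p = 0.0343), as was the basal list (0.0343). Stat6, the transcription factor of interleukin 4 and 13 signalling, stood at 159 ± 11.5 CPM in PBS and 124 ± 2.19 CPM in HDM, and Arg1, an arginase gene, at 22.8 ± 4.97 and 14.6 ± 3.87 CPM. Muc5ac, the gel-forming mucin of goblet cells, had 4 reads in HDM replicate 1 and 0 reads in the other libraries. The inflammasome, interferon response and antigen presentation lists had camera adjusted p = 0.408, 0.694 and 0.694. In HDM replicate 1 Txnip, an inhibitor of thioredoxin, reached 600 CPM against 146 in HDM replicate 2 and 114 ± 9.48 in PBS, and Irf1, an interferon-induced transcription factor gene, 136 CPM against 24.3 and 28.5 ± 1.61. The proliferation list was not called (14 of 20 above 0, camera adjusted p = 0.317). The median of this list was -0.07 in HDM replicate 1 and 0.35 in HDM replicate 2. Mki67 stood at 41.8 CPM in HDM replicate 2 against 20.5 CPM in HDM replicate 1 and 16.5 ± 1.58 CPM in PBS. Over all 4 libraries the list's median log2 fold change was 0.16, and 0.11 after GC correction (camera, adjusted p = 0.670).

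After GC correction camera also called the mitochondrially encoded (adjusted p = 0.000106, lower), dissociation stress (0.00285, higher) and antigen presentation (0.0422, higher) lists. Only 5 of 13 mitochondrially encoded genes were tested, and their sums overlapped (815 and 454 CPM in PBS, 629 and 561 CPM in HDM). Before correction the list medians in HDM replicates 1 and 2 were -0.91 and -0.14 (mitochondrially encoded) and 0.68 and -0.16 (dissociation stress). Those of antigen presentation were 0.45 and -0.23. With GC correction and the replicate block antigen presentation was not called (camera, adjusted p = 0.0606). Without a filter it also called epithelial junctions (0.0168, lower) and macrophage and monocyte (0.000164, lower). Of the 13 macrophage and monocyte genes in that call, only 5 passed the main filter. The summed level of this list overlapped between groups (99.4 and 49.6 CPM in PBS, 126 and 38.1 CPM in HDM). Without HDM replicate 2 the median log2 fold change of epithelial junctions was -0.58. In the main setting the remaining lists were not called: epithelial junctions (adjusted p = 0.0585), mitochondrially encoded (0.0859), alveolar type 2 (0.108), macrophage and monocyte (0.317), ciliated (0.325), basal (0.662), tuft and neuroendocrine (0.694), study genes and sort markers (0.694), endothelial (0.856) and unfolded protein response (0.992). The granulocyte, lymphocyte, dendritic cell and red blood cell lists had fewer than 3 genes tested. Their summed levels were at most 2.06 CPM for granulocyte genes, 6.53 CPM for lymphocyte genes and 0.0674 CPM for red blood cell genes. The dendritic cell sum (729 to 1103 CPM) came nearly all from Cd24a, which epithelial cells also express. In 5 lists, none of them called, the mean and median log2 fold change had opposite signs: study genes, type 2 cytokine response, unfolded protein response, tuft and neuroendocrine, and endothelial. In no list did a gene pass over all genes tested. Adjusted over the list alone, 1 gene passed, Ly6g, the only tested gene of the granulocyte list (19 and 31 reads in PBS, 3 and 1 in HDM). With 1 gene that adjustment changes nothing (edgeR, unadjusted p = 0.0246, and adjusted p = 0.883 over all genes). None of the 6 called lists held with an estimated correlation between genes, as given above, or by fry (adjusted p at least 0.860).

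**Figure D3:**
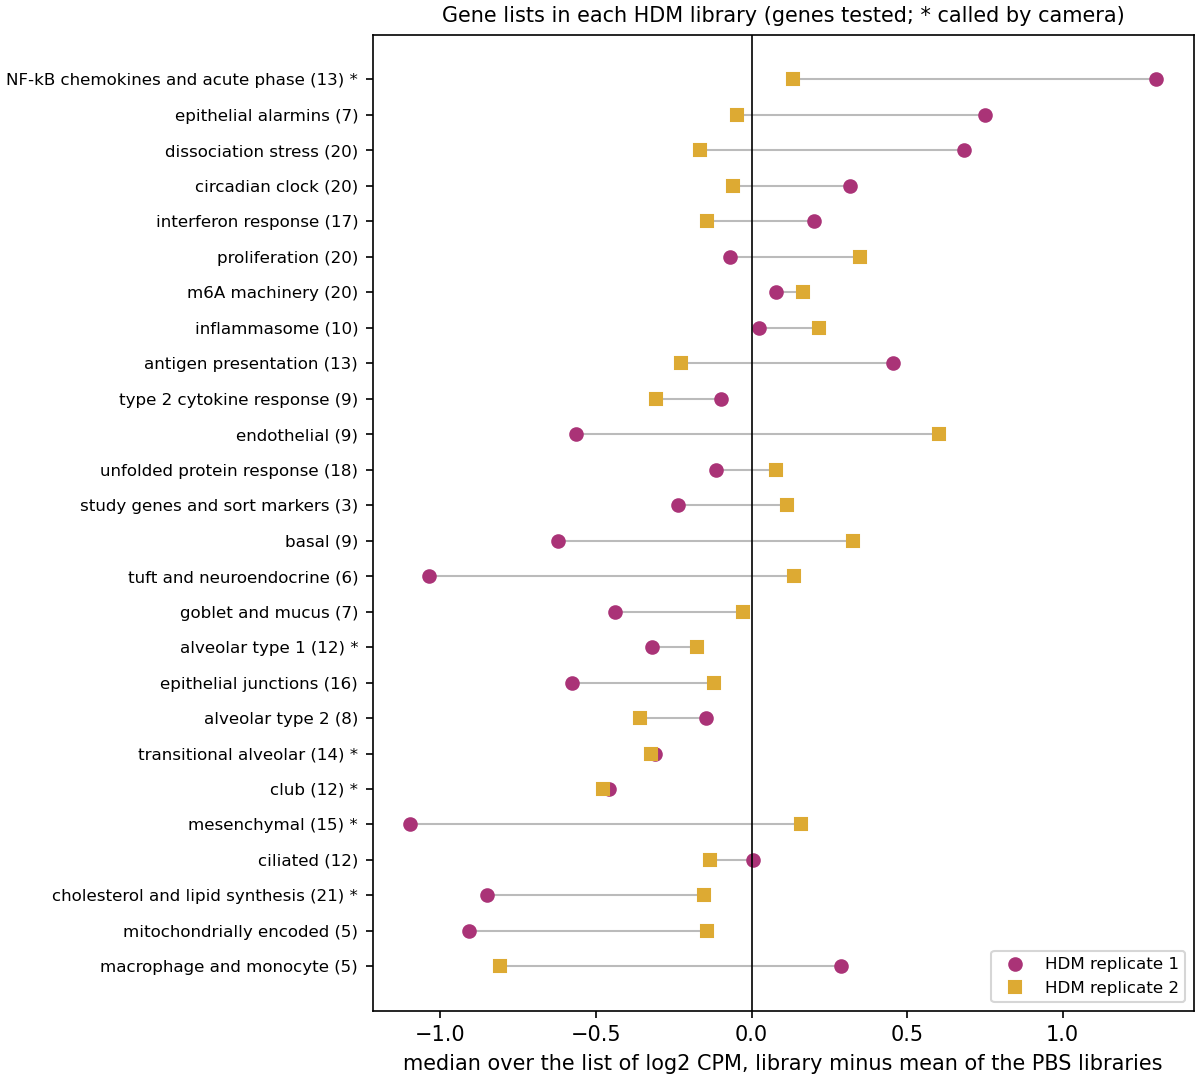
Median over the tested genes of each list of the log2 CPM difference between 1 HDM library and the mean of the PBS libraries, with circles for HDM replicate 1, squares for HDM replicate 2, the number of genes in brackets and a star at each list called by camera over all 4 libraries. The 2 HDM libraries lie close together for the transitional alveolar list (-0.31 and -0.32) and far apart for the mesenchymal list (-1.10 and 0.16).

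The libraries differed in ways that cut across treatment. HDM replicate 1 stood apart on the first principal component, which held 56.5% of the variance, and its correlation with the other libraries (Pearson's r of log2 CPM across genes, which are not independent replicates) was between 0.933 and 0.949, against 0.967 between the PBS libraries and 0.98 between PBS replicate 2 and HDM replicate 2. The difference of HDM replicate 2 from PBS followed GC content (Spearman's rho = -0.55 across 12618 genes), with a median of 0.43 in the lowest of 10 GC bins and -0.34 in the highest, while rho was -0.06 for HDM replicate 1 and 0.06 between the PBS libraries. These latter trends were U-shaped: the bin of lowest GC, the bin of lowest median and the bin of highest GC stood at 0.21, -0.12 and 0.13 for HDM replicate 1 and 0.14, -0.06 and 0.17 for PBS replicate 1 against PBS replicate 2. The departures of HDM replicate 1 from PBS replicate 1 and of HDM replicate 2 from PBS replicate 2 had r = 0.15 across genes, and with the PBS libraries exchanged r = -0.15.

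**Figure D4:**
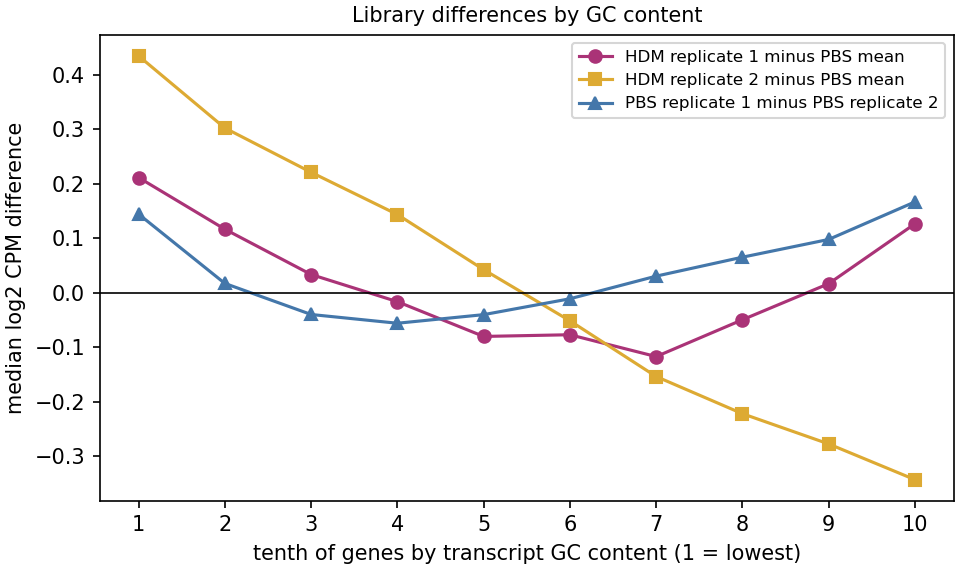
Median log2 CPM difference in 10 equal bins of genes by transcript GC content, for HDM replicate 1 (circles) and HDM replicate 2 (squares) against the mean of the PBS libraries, and for PBS replicate 1 against PBS replicate 2 (triangles). The line of HDM replicate 2 falls from 0.43 in the lowest bin to -0.34 in the highest.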

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

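The GC settings were chosen after the data were seen. The count of genes differing between HDM and PBS was 0 and stayed 0 with the strict filter, median-of-ratios factors, quantile normalization, limma-trend, GC correction, an adjusted p under 0.1 and the added fold limit. It was 1 with DESeq2, 85 without a filter and 577 at an unadjusted p under 0.05. Leaving out each library gave between 0 and 994 genes: 994 without HDM replicate 2, 1 (Gm2058) without HDM replicate 1, 2 (Pou5f1 and Dppa5a) without PBS replicate 1 and 0 without PBS replicate 2. Titles share the numbers 1 and 2, but no label says that a number marks an animal or a day, and the deviations of same-numbered libraries had r = 0.29 across genes. With the replicate block 113 genes were called (93 higher, 20 lower), with GC correction and the block 62, and the block kept all 6 list calls. The count of called lists, 6, was 1 with quantile normalization, 0 with an estimated correlation, 0 with fry and between 2 (without HDM replicate 1) and 7 (without HDM replicate 2 and without PBS replicate 2) with a library left out; the other settings gave 5 to 8. Quantile normalization kept only the cholesterol call, and the strict filter ended only that of NF-kB (adjusted p = 0.0555). All 6 called lists kept their direction under each of the 14 alternatives. GC correction kept 3 of these 6 calls (cholesterol, alveolar type 1 and NF-kB) and added 3 (mitochondrially encoded, dissociation stress and antigen presentation). The log2 fold change of Clock lay between 0.33 (GC correction) and 0.76 (without PBS replicate 1), and that of Ythdf1 between -0.50 (without HDM replicate 2) and -0.00 (without HDM replicate 1). Of 1575 values of the 123 genes of the naming rule under the alternatives, 1437 kept their direction and their side of the threshold, 106 kept their direction and passed it, and 32, from 25 genes, changed sign. Epcam gave 0.043 with GC correction and 0.030 with GC correction and the block, and quantile normalization gave 0.035 for Cd24a and -0.0063 for Zbtb46. All 25 changed sign with some library left out, 16 of them without HDM replicate 1. The lowest and highest values with a library left out were -0.24 and 0.095 (Epcam), -1.36 and 3.57 (Tnf), -0.32 and 5.30 (Hspa1b), -1.04 and 5.20 (Hspa1a), -0.027 and 3.66 (Dnajb1), -0.24 and 2.26 (Irf1), -0.25 and 2.33 (Ddit3), -0.026 and 0.41 (Foxj1), -0.49 and 0.054 (Gcnt3), -0.66 and 0.30 (Galnt6), -0.90 and 2.13 (Ccl20). They were -0.071 and 1.91 (Aim2), -0.83 and 1.39 (Bst2), -0.076 and 0.73 (Tap2), -0.33 and 1.45 (H2-Ab1), -3.81 and 0.029 (H2-DMa), -1.70 and 0.042 (Hydin), -3.17 and 1.05 (Ngfr), -1.12 and 0.035 (Uchl1), -0.26 and 2.72 (Syp). They were -3.95 and 1.0 (Siglec1), -0.34 and 0.26 (Cd24a), -0.32 and 0.49 (Zbtb46), -0.56 and 1.33 (Emcn) and -0.77 and 0.53 (mt-Nd5). The cause of these changes was not tested, except that leaving out a library leaves fewer samples. Other pseudocounts and an untrended variance apply to normalized values and were not run on counts, and a limit to protein-coding genes moves nothing, since the table marks every gene as such. Depth limits what is said of transcripts near 0, such as Ptprc and Muc5ac.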

Other observations

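All tests in this part were chosen after the results were seen, as were the genes named here. GO terms given in the table were tested with camera in place of the fixed lists. Of 277 component terms 8 were called higher and 10 lower in HDM, and of 578 process terms 3 higher and 6 lower (Benjamini-Hochberg within each branch). Matrix terms led: proteinaceous extracellular matrix (187 genes, median log2 fold change -0.36, adjusted p = 6.7e-07) and collagen trimer (42 genes, -0.57, adjusted p = 1.7e-05). The median of the first was -0.66 in HDM replicate 1 and -0.14 in HDM replicate 2. The cytosolic large ribosomal subunit lay higher (55 genes, adjusted p = 0.0303), at 0.56 in HDM replicate 1 and -0.04 in HDM replicate 2. Among processes, cell adhesion (241 genes, adjusted p = 0.0202) and cholesterol biosynthesis (18 genes, adjusted p = 0.0308) lay lower, and DNA repair (259 genes, adjusted p = 0.0403) higher. After GC correction 5 of the component terms and 0 of the process terms stayed called. Medians stayed about as large for cell adhesion (-0.24 before, -0.21 after) and cholesterol biosynthesis (-0.42 and -0.39), so the lost calls do not tie these to GC. The median of DNA repair fell from 0.18 to 0.10. In turn 0 terms of either branch were called with an estimated correlation (adjusted p = 0.902 and 0.932 for the terms named). Without HDM replicate 1 the matrix, ribosomal, adhesion, cholesterol and DNA repair terms named above were not called, and the ribosomal subunit then lay lower. Some called terms shifted by similar amounts in both HDM libraries. Medians in HDM replicates 1 and 2 were 0.19 and 0.13 for DNA repair and 0.41 and 0.31 for pericentriolar material (18 genes). Some other called terms had their shift in HDM replicate 2. The terms chromosome (264 genes) and chromosome, centromeric region (119 genes) lay higher, with medians of 0.24 and 0.33 in HDM replicate 2. In HDM replicate 1 these were 0.065 and 0.0044. Lysosome (248 genes) lay lower, at -0.21 in HDM replicate 2 and -0.03 in HDM replicate 1. None of these chromosome and lysosome terms stayed called after GC correction (camera, adjusted p = 0.553, 0.736 and 0.256).

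Levels over the 4 libraries are given here as means. The highest were Ahnak at 14622 CPM, Actb 11802, Eef1a1 7257, Fn1 6656, Gsto1 5673, Myh9 4410 and Lox 4249 CPM, with Msln at 3810, Krt7 at 3318 and Krt19 at 2317 CPM. The lung epithelial transcription factor genes Nkx2-1 and Foxa1 stood at 48.1 and 67.8 CPM. Members of the fixed cell type lists ranged widely: in PBS, Cyp2f2 of the club list stood at 291 CPM, Emp2 of the alveolar type 1 list at 3331 CPM and Abca3 of the alveolar type 2 list at 189 CPM, while over the 4 libraries Scgb1a1 of club cells stood at 18 CPM, Sftpb of alveolar type 2 cells at 0.234 CPM and Muc5b of mucous cells at 0.300 CPM. The smooth muscle genes Acta2 and Tagln had means of 1119 and 849 CPM. Whether the cells were kept in culture after the sort is not given in the sources used here.

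Heat-shock and NF-kB transcripts were high in HDM replicate 1. All 14 heat-shock factor targets tested were highest in that library, with a median log2 difference of 1.71 from the other 3 libraries. The levels argue against leukocytes carried through the sort. In HDM replicate 1 the 10 pan-leukocyte genes, 1 of them high enough to be tested, summed to 0.539 CPM. In PBS replicates 1 and 2 and HDM replicate 2 they summed to 3.43, 1.61 and 0.588 CPM. The macrophage list sum was highest in HDM replicate 1 (126 CPM against 99.4, 49.6 and 38.1), with 121 CPM from Cd68. C1qa, Csf1r and Ptprc had at most 1 read there. The lymphocyte list sum was also highest in HDM replicate 1 (6.53 CPM against 4.32, 3.45 and 3.39), with 5.19 CPM from Gata3. A response to tissue dissociation stays open: 11 of 16 immediate-early genes were highest in that library (median 0.60, upper quartile 1.20), less than the targets, but no table gives the proportion in which dissociation raises them. Handling of that library and a response to HDM in this sample also stay open and were not tested. In HDM replicate 2 the heat-shock factor targets had a median log2 difference of -0.05 from PBS, and 6 of the 14 lay above both PBS libraries. The median of the NF-kB list there was 0.13.

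AT-rich genes, Clock among them, were higher in HDM, most of all in HDM replicate 2. The tables argue against transcript length as the source, since within 10 bins of length the correlation of GC with the difference of HDM replicate 2 from PBS kept a median of -0.55. Among 500 genes of like GC and level, Clock lay at percentile 90.8 in HDM replicate 2 and 85.8 in HDM replicate 1, inside the middle 95% of these genes, whose medians were 0.34 and 0.12. With GC correction the log2 fold change of Clock went from 0.62 (standard error 0.23) to 0.33 (0.21). Clock itself differed from PBS by 0.63 in HDM replicate 2 and 0.62 in HDM replicate 1, against the like genes' medians of 0.34 and 0.12. The typical shift of genes of like GC thus covers only part of its difference, least in HDM replicate 1. The spread of these genes holds other differences between genes besides GC, so the percentiles cannot say what the rest is. With 2 libraries per treatment, a response to HDM cannot be told apart from such differences.

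Several pluripotency transcripts were found in 3 of the 4 libraries: Pou5f1 at 16.9, 0, 25.6 and 8.96 CPM and Nanog at 18.8, 0.468, 23.3 and 8.37 CPM in PBS replicates 1 and 2 and HDM replicates 1 and 2. Of 16 pluripotency genes with at least 20 reads in PBS replicate 1, which had no HDM, 15 were under 1 CPM in PBS replicate 2, so these did not follow treatment, and Tfcp2l1 was level (79.3, 73.6, 87.1 and 88.1 CPM). Whether the 15 share 1 pluripotent mouse source, as cells or as reads carried over, stays open: the SD over them of the log2 ratio of HDM replicate 2 to PBS replicate 1 was 0.433, at percentile 7.27 of random sets of like level, where under 5 was asked for. Over the 15, the median log2 ratio of HDM replicate 1 to PBS replicate 1 was -0.13. The upper quartile of the log2 ratio of HDM replicate 2 to PBS replicate 1 was -0.88, so most were lower there. The SD does not measure such a shared shift, so that test alone cannot decide. Reads shared with pseudogenes were not tested.

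Gm11175 stood at 1033 CPM in HDM replicate 1 and at most 1.27 CPM elsewhere, and Mrs2 at 894 CPM there and at most 40.9 CPM elsewhere, with no strand setting given to part overlapping genes. Myog stood at 0.404 CPM in HDM replicate 1 and between 4.11 and 7.42 CPM elsewhere. The replicate number, fitted beside treatment, had 430 genes called by edgeR (159 higher in number 2). Krt5 stood at 26.5 and 34.8 CPM in the number 1 libraries and 84.1 and 78.5 CPM in the number 2 libraries of PBS and HDM.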
